A study of Mus musculus with 2 samples.

How the data were processed

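Gene expression was measured on 1-colour (Cy3) Agilent mouse arrays in cells cultured to osteoclasts, the multinucleated cells that resorb bone. Per the labels, nonadherent mouse bone marrow cells were cultured with macrophage colony-stimulating factor (M-CSF), the adherent monocyte/macrophage precursors were kept, and these were then cultured with M-CSF and RANKL, the cytokine that drives osteoclast formation. The series analysed here has 2 arrays, 1 from wild type and 1 from Dnmt3a knockout cells, both from female C57BL/6 mice, and each array took its group from its genotype label. Which allele was used, and which cells had lost the gene, is not given in the sources used here.

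Per the file headers, the authors' scanner files hold the intensity of each spot after background subtraction and spatial detrending within the array by Agilent Feature Extraction 10.10.1.1 (protocol GE1_1010_Sep10, probe positions on mm9). The submitters' processing notes name Feature Extraction 9.1, and which of these versions made the files was not settled. The deposited intensity is not normalized between arrays. Per the file headers, the same files give the scanner software's error of each processed signal, marks for spots well above background, saturated or uneven, and the median intensity of the spot and of its surroundings. The deposited value table was set against the scanner values by spot number: it is the processed intensity on a linear scale, multiplied by 1 factor per array (median 1.55 for wild type, 1.54 for the knockout), with no centring and no ratio between arrays. Its column medians were 59.6 and 66.5, and how the factor was chosen stays unknown. It served as an alternative. Both arrays lay on 1 slide and were scanned together, so the comparison was made within a slide and a scan, and no other batch was known.

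The main setting was fixed before the data were examined: log2 of the processed signal minus the log2 of each array's 75th percentile over the 59305 spots that were not controls. Spots marked as uneven or as population outliers on either array were left out (157 such spots on the wild type array and 172 on the knockout array), and spots of a probe were averaged on the log2 scale. No spot was saturated. Of the 55649 probes left, 27224 (48.9%) were named by matching the unversioned accession in the file to a RefSeq gene table of assembly GRCm38.p6, used for names only. The files hold no column of gene names, which the planned naming had assumed. Another 16181 probes are named in the files by genomic position, and 12244 probes matched no gene and stay unnamed here. The named probes covered 20654 genes, of which 5474 had several probes, and the brightest probe by the mean of both arrays stood for its gene.

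A gene counted as measured on both arrays when its probe was well above background there in most of its spots, which held for 13479 genes. For a gene above background on 1 array only, the fold is a bound: the bright signal over the higher of the dim probe's own signal and the lowest signal among probes well above background on the dim array, after scaling. Differences are knockout minus wild type throughout. The error beside a difference is the scanner software's error of both spots carried to log2, with a median of 0.20. It covers the measurement of a spot and not the variation between cultures or mice. It is the software's own figure and exceeds the median SD of the difference between repeated spots (0.07). A difference within it is therefore not shown to be absent. With 1 array per genotype there is no replicate, so no test across samples was made and no p-value is given.

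Gene lists (29) were fixed before the data were examined, for osteoclast function, DNA methylation, metabolism, immune responses, proliferation, other cell types and RNA handling. For each, the median difference of the members measured on both arrays was placed among 10000 random lists of the same size, drawn from 20 bins of mean level so as to match the members, and a list was called higher or lower when it lay outside the central 95% of them. This percentile describes these 2 arrays, members of a list are not independent, and the 29 lists were not corrected for their number. A few genes sit on more than 1 list, among them Fos, Jun, Dcn, Gapdh, Gusb, Pgk1 and Sdha.

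The genes named in the text followed a rule fixed beforehand: a set of genes of interest; the 12 genes with the largest rise and the 12 with the largest fall among genes measured on both arrays with a mean level at or above the median, leaving out clone-like names; the 5 genes with the largest bound in each direction; and for each list its 2 highest and 2 lowest members. Genes outside it are said to be so, and the values of some genes that the rule names are not reported here.

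The calling of genes and lists was tried on simulated differences of 13475 genes of this comparison. Each gene got noise of about the median scanner error (0.20), below the SD of 0.37 over the measured differences. Background, scaling, bounds and spot defects were not simulated, so the figures check the calculation and are no error rates for these arrays. Of 100 genes with a log2 change of 1.5, 98% were recovered, and of 100 genes with a change of 3, 100%. Past 2-fold lay 0% of the 13275 other genes, which include a list of 20 shifted by 0.4. That list lay above all random lists, and 3% of 200 random lists were called.

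The alternatives were normexp background correction (offset 50), centring on the median, quantile normalization, loess of the difference on the mean level (span 0.3), scaling to the 8 E1A spike-in probes, the deposited value table, no filter on dim probes, genes on 1 array entered at their bound, only genes at or above the median level, the median over a gene's probes, random lists not matched on level, and a threshold of 3-fold. Normexp was planned on mean intensities, which the files do not hold, and was run on the median intensity of the spot and its surroundings. Leaving out the spots in array rows 1 to 128 was added after the data were seen. Calculations used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.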

Results

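RNA of wild type and Dnmt3a knockout cells cultured to osteoclasts was hybridised to 1 array each. Of 59305 spots per array, 31272 (52.7%) were well above background on the wild type array and 35398 (59.7%) on the knockout array. The median signal of the 308 negative control spots was 6.06 and 4.24, and the lowest signal of a probe well above background was 25.8 and 17.7. Across the 28203 probes above background on both arrays, which are not independent replicates, Pearson's r between the arrays was 0.992. Among 259 probes spotted repeatedly, the median SD of the log2 difference between the arrays was 0.07, and 0 of 2485 such differences lay 2-fold or more from their probe's mean. Only unmarked spots well above background on both arrays entered, from probes with at least 8 of them. Spots bright on 1 array only are therefore not covered. The number of arrays, with no replicate of either genotype, limits the precision of every value. Xist, the RNA of the inactive X chromosome, was well above background on both arrays (difference 0.09, SE 0.20), and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were not well above background on either. These genes check the labelled sex and lie outside the naming rule.

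The comparison asks how gene expression differs in osteoclast cultures of cells without Dnmt3a, a de novo DNA methyltransferase. Dnmt3a itself was 3.79-fold lower on the knockout array. Genes of the interferon response were higher there, with a median of 1.72-fold and all 28 measured members above 0, and so were markers of macrophages (1.40-fold) and of neutrophils and their granules (1.38-fold). Effector genes of osteoclasts were lower, with a median of 1.41-fold and 21 of 22 members below 0, as were markers of stromal cells and osteoblasts (1.44-fold) and genes of the tricarboxylic acid cycle (1.27-fold). These directions are relative to the bulk of the genes: scaling to the spike-in probes instead lowers every difference by 0.53 on the log2 scale and moves the median of all measured genes from 0.01 to -0.52, so that differences between 0 and 0.53 become negative. The shift of 0.53 is the median of 8 spike-in probes, which ranged from 0.30 to 0.73. The sign of a difference within that range therefore depends on the spike-in probe used.

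The Dnmt3a probe gave a signal of 7042 on the wild type and 1822 on the knockout array, a log2 difference of -1.92 (SE 0.20). It stayed well above background on the knockout array. It is the gene's only probe here, and whether it lies in the deleted part is not known, so it checks the label only as far as the transcript is lost. The other DNA methyltransferases differed by less than the scanner error: Dnmt1 by -0.09, Dnmt3b by -0.16 (3 probes between -0.16 and 0.11) and Dnmt3l by 0.04. That error exceeds the median SD of 0.07 between repeated spots, so it does not show these genes to be equal on both arrays. Over the 18 genes of the DNA methylation machinery the median difference was -0.04, inside the range of matched random lists (-0.14 to 0.15). Dnmt3a was the only member past 2-fold, and Uhrf1 (-0.32), Mbd2 (0.23) and Zbtb4 (0.36) were the next at either end. Mat2a, which makes the methyl donor S-adenosylmethionine, differed by -0.29 (SE 0.20; its other probe -0.13).

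Of the 13479 genes measured on both arrays, 111 were at least 2-fold higher and 98 at least 2-fold lower on the knockout array, so that 53.1% of the differences past 2-fold were upward. This share depends on the scaling and was 39.8% after quantile normalization and 1.73% with spike-in scaling. The SD of the difference over all these genes was 0.37. Of these genes, 6 of the 111 and 4 of the 98 belonged to a fixed list. The share over all measured genes is not given here, so these counts show neither a surplus nor a lack of list genes. At or above the median level, 27 genes were at least 2-fold higher and 7 at least 2-fold lower. Without the spots of array rows 1 to 128, an alternative chosen after the data were seen, the counts over all levels were 65 and 48. They were 42 and 26 after normexp background correction, and 1184 and 466 with no filter on dim probes.

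Among the well expressed genes, the largest rise was that of Marco, a scavenger receptor of macrophages (log2 difference 1.47, 2.78-fold, SE 0.20). Vsig4, a complement receptor of tissue macrophages, was at 1.32. The interferon-induced chemokine Cxcl10 reached 1.19, the interferon-induced kinase Cmpk2 1.12 (its other probe 0.92), and Mmp8, the neutrophil collagenase, 1.08. Npcd (1.22), Fryl (1.14), Med13 (1.13) and the neuronal RNA-binding protein Elavl4 (2.15-fold) rested on 1 probe each above background. So did Marco, Vsig4, Cxcl10 and Mmp8, which have no further probe. For Armcx3 (1.38), Nhlh1 (1.24) and Dcaf12l2 (1.08), a further probe of the gene gave -0.06, -0.32 and -0.27, so the probes disagree. The spots of Vsig4, Nhlh1, Npcd, Cmpk2 and Elavl4 lie in array rows 1 to 128, whose share of genes past 2-fold is given at the end.

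Among the largest falls after Dnmt3a were those of Tnfrsf11a, which encodes RANK, the receptor of RANKL (-1.20, 2.30-fold lower, SE 0.20), the ubiquitin hydrolase Uchl1 (-1.13) and the integrin chain Itgav (-1.12, its other probe -0.58). Msln (-1.03) and Ccn5 (-1.03) were also past 2-fold. The thrombin receptor F2r (-0.99), the procollagen proteinase Bmp1 (-0.99, its other probe -0.42), the chemokine Cxcl12 (-0.98, its other probe -1.30), the alkaline phosphatase Alpl (-0.98) and the collagen chain Col3a1 (-0.95) fell just short of it. Tnfrsf11a, Uchl1, Msln, Ccn5, F2r, Alpl and Col3a1 had 1 probe each. The spots of Msln, Bmp1, Alpl and Col3a1 lie in rows 1 to 128.

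**Figure D1:**
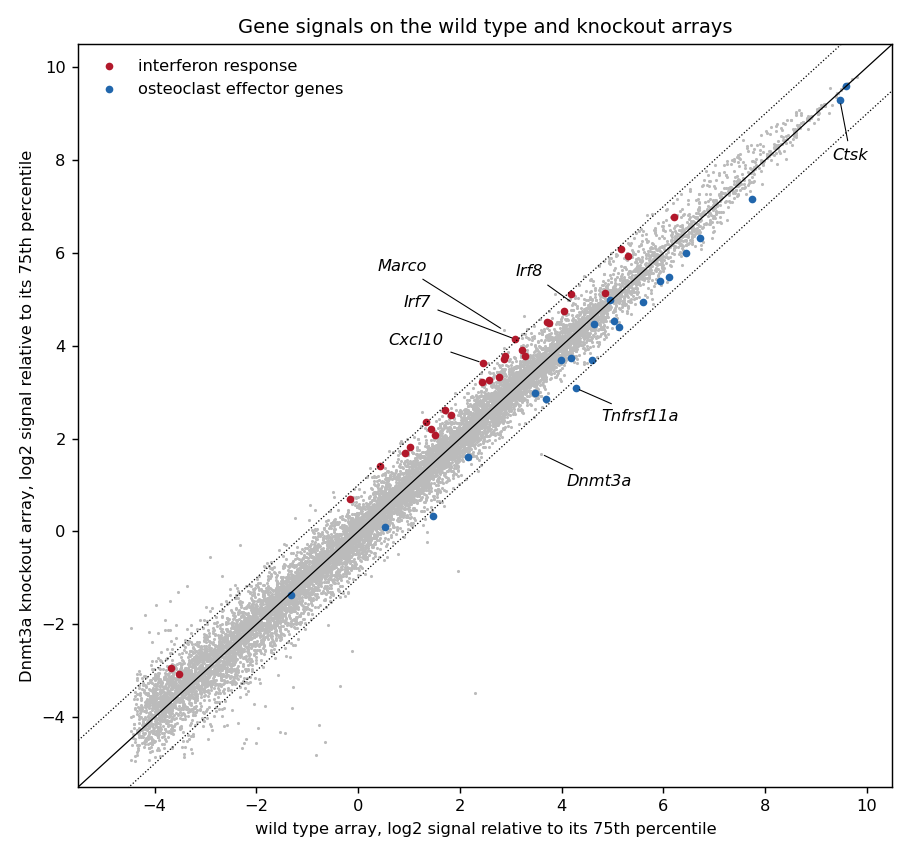
Log2 signal of 13479 genes measured on both arrays, wild type on the x axis and Dnmt3a knockout on the y axis, each relative to its array's 75th percentile (1 array each). The solid line marks equality and the dotted lines 2-fold; the 28 interferon response genes (red) lie above equality, 21 of 22 osteoclast effector genes (blue) lie below it, and Dnmt3a lies below the lower dotted line at a log2 difference of -1.92.

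Osteoclast effector genes had a median difference of -0.50, below all 10000 matched random lists (central range -0.09 to 0.15). Tnfrsf11a and Itgav were past 2-fold. The calcitonin receptor Calcr was at -0.84, the osteoclast-associated collagen receptor Oscar at -0.72, the integrin chain Itgb3 at -0.64 (its other probe -0.50) and the gelatinase Mmp9 at -0.58 (SE 0.06). The fusion genes Dcstamp (-0.54), Ocstamp (-0.49) and Atp6v0d2 (-0.62, its other probe -0.76) were lower as well. Calcr, Oscar, Mmp9, Dcstamp and Ocstamp had 1 probe each. Acp5, the tartrate-resistant acid phosphatase, differed by -0.00, the collagen-degrading protease Ctsk by -0.18 and Plekhm1 by 0.02, all within the scanner error. The difference of Ctsk was larger than the median SD of 0.07 between repeated spots.

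Activators of osteoclast transcription were lower by a smaller amount, with a median of -0.18 over 19 genes (random lists -0.12 to 0.16, percentile 0.31). Nfatc1, the master transcription factor of osteoclasts, was at -0.55 (its other probe -0.23), Prdm1 at -0.46 and Fos at -0.35, with Fosl2 (-0.62, its other probe -0.18) and Fosl1 (-0.59) at the low end. Tfe3 (0.33) and Creb1 (0.36, its other probe -0.24) were at the high end. Factors through which osteoclasts act on bone-forming cells had a median of -0.34 over 13 genes (random lists -0.19 to 0.20, percentile 0.08), led by Efnb2 (-0.93) and Sphk1 (-0.75), while Igf1 (0.47) and C3 (0.57) were positive. The list of proton pump and lysosome genes held members that went both ways (28 genes, median -0.02, random lists -0.06 to 0.14). Split after the values were seen, the 15 genes of the proton pump (V-ATPase) had a median of -0.25 with 12 of them below 0 (random lists -0.11 to 0.18, percentile 0.03), Atp6v1h being lowest at -0.43. The 13 lysosome genes had a median of 0.11, inside the range of random lists (-0.12 to 0.20), with Ctsl at 0.45 (row 288 and column 156, in the corner given below for Aurkb) and Lamp2 at 0.47.

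Irf8, a transcription factor that restrains osteoclast formation, was 1.61-fold higher on the knockout array (log2 difference 0.68, SE 0.20, 1 probe) and remained positive, at 0.15, with spike-in scaling. Its 0.68 lies within the range of the single spike-in probes (0.30 to 0.73). Bcl6, a further repressor, was at 0.33 in the main setting and at -0.21 with spike-in scaling. The 10 measured repressors of osteoclast formation had a median of 0.11, inside the range of random lists (-0.18 to 0.20): Hdac7 was highest (0.87), and Tnfaip3 (-0.47) and Id1 (-0.40) were lowest. Among genes at or above the median level the list's median was 0.26, above the central range of random lists. Csf1r, the receptor of M-CSF, differed by 0.10 (3 probes between 0.10 and 0.50) and by -0.43 with spike-in scaling.

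The interferon response genes stood farthest from the random lists, with a median of 0.79 against a central range of -0.09 to 0.13, and their median was still 0.25 with spike-in scaling. Of the 28 genes 3 were past 2-fold, Cxcl10, the transcription factor Irf7 (1.05) and the guanylate-binding protein Gbp2 (1.03, row 15, named after its value was seen), and the lowest were Oas2 (0.29) and Cxcl9 (0.45). Genes of antigen presentation on MHC class II had a median of 0.42 over 13 genes, all above 0 (random lists -0.15 to 0.21, percentile 99.96; median -0.11 with spike-in scaling). The costimulator Cd86 (0.78) and the class II transactivator Ciita (0.64) led them, and Cd74 (0.10) and H2-Eb1 (0.15) were lowest. Inflammatory cytokines and chemokines went both ways, with a median of 0.16 over 19 genes at percentile 97.4, just inside the range of -0.14 to 0.16. Il1b (0.88) and Ccl6 (0.84) were highest, and Tgfb2 (-0.85) and Vegfa (-0.72) were lowest.

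Markers of other cell types moved in several directions. Macrophage markers had a median of 0.48 over 21 genes, 20 of them above 0 (random lists -0.10 to 0.14, above all 10000; median -0.05 with spike-in scaling): after Marco came the Fc receptor Fcgr1 (0.89), and Cd36 (0.07) and Itgam (-0.27, with a further probe at 0.32) were lowest. Markers of neutrophils and granules had a median of 0.47 over 16 genes, all above 0 (random lists -0.13 to 0.17, above all 10000; median -0.07 with spike-in scaling), from Csf3r (0.02) and Elane (0.15) to Retnlg (0.70) and Mmp8. Dendritic cell markers had a median of 0.35 over 12 genes (random lists -0.20 to 0.23, percentile 99.75; median -0.18 with spike-in scaling), with Cd209a (0.77) and Batf3 (0.64) highest and Fscn1 (-0.39) and Itgax (-0.15) lowest. At or above the median level the dendritic median was 0.23 and inside the range of random lists.

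Stromal and osteoblast markers had a median of -0.53 over 18 genes, 15 of them below 0, which lay below all 10000 random lists (-0.14 to 0.16). Cxcl12 and Alpl were lowest, while the leptin receptor Lepr (0.16) and the osteocalcin gene Bglap2 (0.84, SE 0.30, near background and with a near-identical copy in the genome) were highest. Erythroid markers had a median of -0.43 over 7 genes (random lists -0.28 to 0.29, percentile 0.41), with the globins Hbb-b2 (-0.73) and Hba-a1 (-0.63), whose near-identical copies make them uncertain (the spot of Hbb-b2, row 269 and column 153, also lies in the corner of the array given below for Aurkb), Slc4a1 (-0.10) and Epor (0.33). No filter on dim probes put this list inside the range of random lists, with a median of -0.43.

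The remaining cell type lists were not called. B lymphocyte markers had a median of 0.20 over 11 genes (percentile 95.2), between Ebf1 (-0.72) and Vpreb1 (0.46). T and NK lymphocyte markers had a median of 0.15 over 10 genes (percentile 91.2), between Cd5 (-0.68) and Cd2 (0.72). Megakaryocyte and platelet markers had a median of 0.19 over 11 genes (percentile 96.1), with Pf4 at 0.83 and Gp1ba at -0.08. Mast cell and basophil markers (0.13 over 6 genes, percentile 75.3; Prss34 0.77, Mcpt8 -0.32) and endothelial markers (0.09 over 7 genes, percentile 73.5; Eng 0.69, Plvap -0.63) were mixed.

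Mitochondrial genes were lower by a small and even amount. All 53 measured genes of oxidative phosphorylation lay below 0, with a median of -0.22, below all 10000 random lists (-0.01 to 0.11). Cytochrome c1 (Cyc1, -0.52) and cytochrome c (Cycs, -0.47) were lowest, and Cox5a (-0.11) and Ndufa2 (-0.09) were nearest to 0. In the tricarboxylic acid cycle 19 of 20 genes lay below 0, with a median of -0.34, below all 10000 random lists (-0.09 to 0.16): Idh3a (-0.59) was lowest, and the cytosolic Idh1 (0.23) was the exception. Glycolysis genes had a median of -0.15 over 21 genes (random lists -0.09 to 0.15, percentile 0.5), with Slc2a1 (-0.36) and Aldoc (-0.35) lowest and Hk3 (0.58) and Pfkfb3 (0.59) highest. After normexp background correction the glycolysis median was -0.0445 and no longer outside the random lists.

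Genes of methionine and one-carbon metabolism had a median of -0.10 over 22 genes (percentile 4.47, random lists -0.12 to 0.15) and were not called, with Mtap (-0.55, row 286 and column 162, also in that corner) and Mthfd2 (-0.55) lowest and Mtrr (0.31) near the high end. At or above the median level their median was -0.29, below the range of random lists. Cholesterol synthesis genes were not called either (median -0.05 over 21 genes, percentile 18.2), with Insig1 (0.21) and Mvd (0.43) at the high end.

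Imprinted genes and germline genes, classes whose expression is linked to DNA methylation, were not called in the main setting, but each was called in 1 alternative. Of 23 imprinted genes on the array 12 were measured on both arrays, with a median of -0.12 (percentile 8.49, random lists -0.19 to 0.22). Sgce (-0.95) and Plagl1 (-0.75, with probes up to 0.32) were lowest, and Gnas (0.05, a further probe -0.30) and Slc22a18 (0.12) were highest. With no filter on dim probes the imprinted median was -0.19, below the range of random lists. Of 24 germline genes 7 were measured on both arrays, with a median of 0.16 (percentile 85.0, random lists -0.34 to 0.32). The dim genes Smc1b (1.15, SE 0.35) and Piwil2 (0.81, SE 0.34) were highest, and Ddx4 (-0.29, row 359 and column 150, in the corner given below for Aurkb) and Taf7l (-0.10) were lowest. Another 3 germline genes were above background on the knockout array only, but each had a bound of 0. Their own differences (-0.05, -0.07 and -0.03) were slightly negative, so they show no rise. On the wild type array only there was 1, with a log2 bound of -0.72. Without the spots of rows 1 to 128 the germline median was 0.47, above the range of random lists.

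Proliferation and RNA handling gave no called list. Cell cycle genes had a median of 0.03 over 31 genes (percentile 71.7), with Mki67 (0.51) and Ccnb2 (0.40) highest and Mcm6 (-0.73) low; Aurkb was 2.83-fold lower, but its spot lies at row 372 and column 155, in a corner of the array (rows from 257 and columns from 145) that holds 9 of the 98 genes at least 2-fold lower and 1 of the 111 at least 2-fold higher, 9.18% (exact 95% interval 4.29 to 16.7) and 0.901%, against 4.12% of all genes measured on both arrays. Immediate early and heat shock genes had a median of 0.08 over 17 genes (percentile 82.2), between Hspb1 (-0.52), Hsp90aa1 (-0.36), Atf3 (0.51) and Ier3 (0.58). Housekeeping genes had a median of 0.04 over 15 genes (percentile 48.0), between Sdha (-0.31), Gapdh (-0.16), B2m (0.24) and Hprt (0.30).

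**Figure D2:**
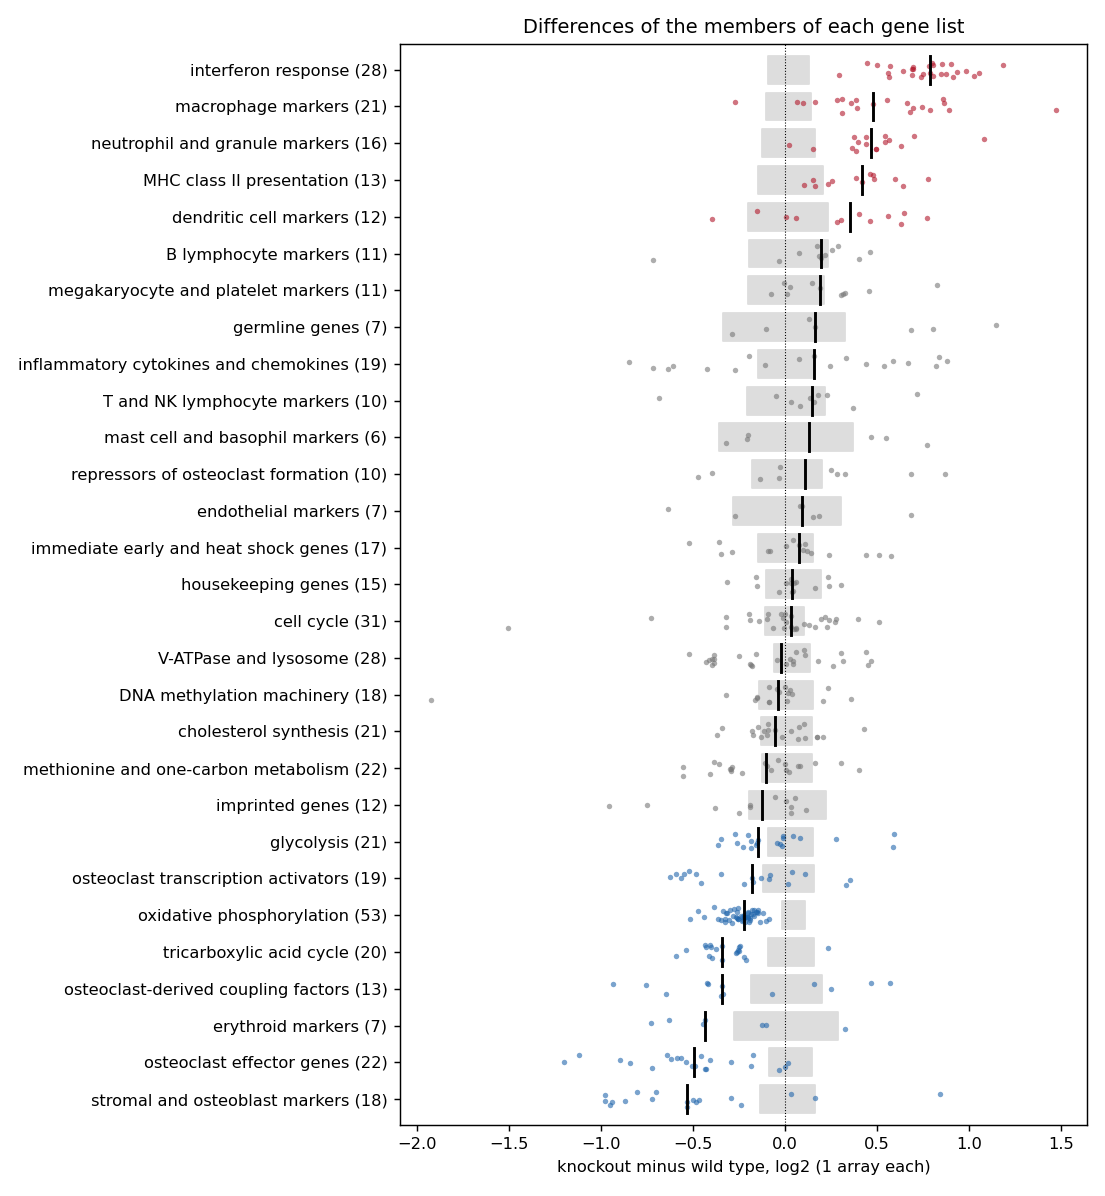
Differences between the knockout and wild type arrays (log2, x axis, 1 array each) of the measured members of each of the 29 gene lists, with the number of members beside each name. Points are genes, black bars list medians and grey bands the central 95% of 10000 matched random lists; 5 lists are called higher (red) and 8 lower (blue), and with spike-in scaling the medians of the macrophage (-0.05), neutrophil (-0.07), MHC class II (-0.11) and dendritic cell (-0.18) lists become negative. That scaling uses the median of spike-in probes that range from 0.30 to 0.73, so these signs depend on the probe used.

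Genes above background on 1 array only were 1122 on the knockout and 170 on the wild type array, and in 111 and 126 of them the bound was at least 2-fold. The latter counts were 31 and 45 after normexp background correction, and 29 and 43 without the spots of array rows 1 to 128. On the knockout array only, the largest bounds included those of Stoml3 (at least 17.8-fold higher), Cyp27b1 (at least 12.8-fold), Ndst4 (at least 11.8-fold) and Lrfn5 (at least 9.11-fold). On the wild type array only, they were those of Hspbap1 (at least 32.9-fold lower on the knockout array), Tac2 (at least 21.4-fold), Gpr39 (at least 18.5-fold), Kynu (at least 16.0-fold) and Iqcj (at least 13.4-fold). The spots of all of these but Hspbap1 and Tac2 lie in array rows 1 to 128, and those of Hspbap1 (row 319, column 153) and Tac2 (row 375, column 156) in the corner named for Aurkb. Of the 237 genes with a bound of at least 2-fold, 72.2% (exact 95% interval 66.0 to 77.8) lie in rows 1 to 128, against 34.0% of genes measured on both arrays. Of the genes measured on both arrays, 44.1% of those at least 2-fold higher and 52.0% of those at least 2-fold lower lie there (intervals 34.7 to 53.9 and 41.7 to 62.2). Of the list genes named above with differences of at least 0.5 in size, those in rows 1 to 128 also include Atp6v0d2, Efnb2, Mthfd2, Hk3, Mki67, Ciita, Tgfb2, Retnlg, Cd2 and Bglap2. The row of a gene is that of its probe's first spot. Mmp9, C3 and Il1b have their first spot there too, but their small errors (0.06, 0.06 and 0.07) are those of probes spotted repeatedly. The rows of their other spots are not given here.

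**Figure D3:**
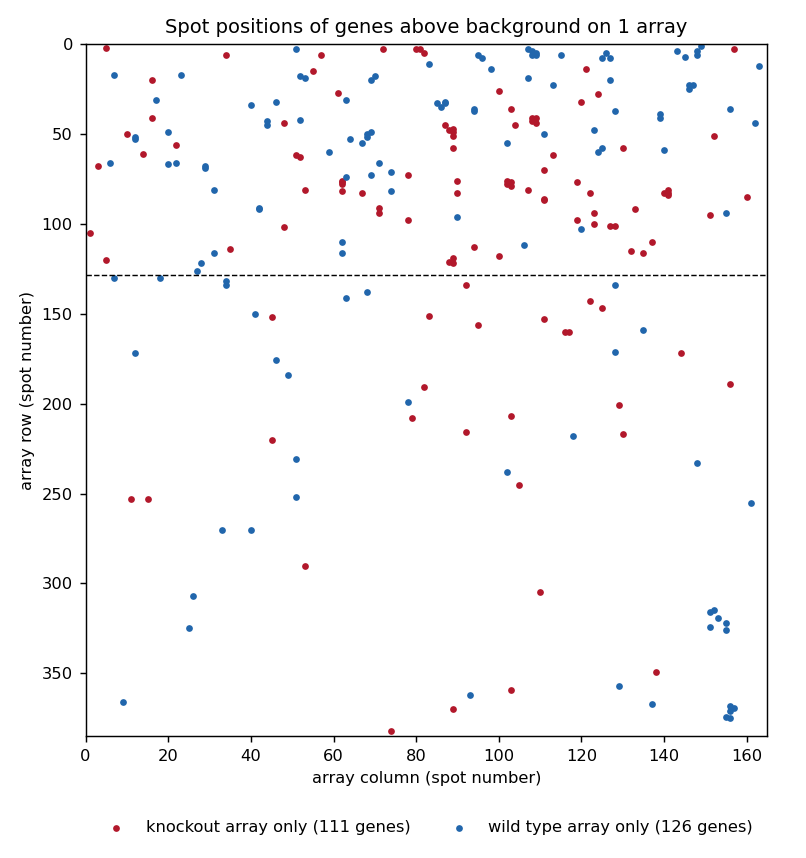
Array row (y axis) and column (x axis), in spot numbers, of the 237 genes above background on 1 array only with a bound of at least 2-fold, 111 on the knockout array (red) and 126 on the wild type array (blue). The dashed line closes row 128; 72.2% of the points lie above it, and 11 of the wild type points and 0 of the knockout points lie in the lower right corner (rows from 257 and columns from 145).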

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

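The tests of spot position and of background were chosen after the result was seen; the test of further probes was written down before its result.

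Data outside the comparison of named genes held a pair of signals. Of the 16181 probes named by genomic position, 5250 were above background on both arrays, and 77 of these were at least 2-fold higher and 77 at least 2-fold lower on the knockout array. The largest differences were those of probes on chromosome 3, 85842798 to 85887216 (mm9, log2 difference 3.61, SE 0.32), and on chromosome 15, 32167516 to 32174417 (mm9, -3.63, SE 0.28); the spots lie at array rows 42 and 373, and 45 of the higher and 53 of the lower probes lie in rows 1 to 128. The 8 E1A spike-in probes, which should be equal on both arrays if equal amounts of spiked RNA were labelled, were higher on the knockout array after scaling, by a median of 0.53 (0.30 to 0.73).

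The genes above background on 1 array only with a bound of at least 2-fold (111 on the knockout and 126 on the wild type array) gather in part of the array. A lower background on the knockout array does not account for them. The bound of a knockout gene is taken over at least the lowest signal well above background on the wild type array. A lower such signal on the knockout array therefore cannot produce it. That signal was 0.52 lower there on the log2 scale, and setting this against the log2 bound of 1 adds no test. A lower background there makes no prediction for the genes above background on the wild type array only, so their presence does not bear on it. A genotype difference of the genes with such a bound, on either array, would also show in their further probes. Among the 58 such genes with a further probe, 5.17% had it above background on the bright array. Among 557 genes of similar level measured on both arrays the share was 53.0%. Genes with any probe above background on the dim array were left out of the set beforehand, which can lower its share. The comparison genes had no such filter, and its effect was not tested, so the gap does not decide the question. Spot defects in rows 1 to 128 are a candidate explanation, since 72.2% of the genes lie there (interval 66.0 to 77.8) against 34.0% of genes measured on both arrays, and dim control spots (probes with a median signal under 15) were well above background more often there, in 4.72% against 0.593% of wild type spots and 6.80% against 2.31% of knockout spots. Open is whether any of the genes with a bound of at least 2-fold differ by genotype. Open too is the cause of the cluster in the lower right corner of the array, which holds 11 of the 126 wild type genes and 0 of the 111 knockout genes. At any bound, 1122 genes were above background on the knockout array only, against 170 on the wild type array only. The lowest signal well above background, 0.52 lower on the knockout array, would give a surplus in this direction among genes with small bounds. How much of the surplus it accounts for was not tested.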

How the results depend on the processing

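Leaving out the spots of rows 1 to 128 was chosen after the data were seen; the other alternatives were planned. Of the alternative values for counts, list medians and the Dnmt3a difference, 363 stayed and 22 moved. Another 12 passed the threshold newly, 3 no longer passed it and 0 reversed against the random lists. A list median stayed when its call against the random lists was unchanged, whatever the sign of the median. Spike-in scaling, median centring and the deposited table shift all differences by nearly the same amount (SD over genes 0.37 in each). A list's place among random lists could therefore hardly change under them. For the genes of interest fixed beforehand 204 values stayed and 23 moved, by the common shift of spike-in scaling in all but Mmp9 after quantile normalization (-0.68) and Csf1r by the median over probes (0.35). The interferon, macrophage, osteoclast effector, oxidative phosphorylation and stromal lists lay outside all random lists under each of the 12 alternatives. For the alternatives that shift all differences alike, this followed from the main setting. Spike-in scaling makes the macrophage median negative (-0.05), as it does for the neutrophil (-0.07), MHC class II (-0.11) and dendritic (-0.18) lists. No paired analysis was possible because each genotype has 1 array and the results come from no test.

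Against 111 genes higher and 98 lower at 2-fold, the counts were 42 and 26 after normexp, 18 and 1024 with spike-in scaling, 1184 and 466 with no filter on dim probes, 222 and 224 with genes on 1 array at their bound, 27 and 7 at or above the median level, 65 and 48 without rows 1 to 128, and 15 and 21 at 3-fold. Genes with a bound past the threshold on the knockout array only (111) were 31 after normexp, 58 with spike-in scaling, 29 without rows 1 to 128 and 53 at 3-fold; those on the wild type array only (126) were 45, 43 and 81 after normexp, without these rows and at 3-fold, and rose to 170 with spike-in scaling and 163 after quantile normalization. Bounds have no value with no filter, at their own bound, or by level. The share of upward calls was 46.2% after median centring, 44.3% after loess and 45.7% in the deposited table.

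Lists newly past the threshold were the osteoclast repressors with no filter (0.25) and at or above the median level (0.26), imprinted genes with no filter (-0.19), methionine metabolism at or above the median level (-0.29), by the median over probes (-0.17) and without rows 1 to 128 (-0.23), inflammatory cytokines after normexp (0.16), quantile normalization (0.13), loess (0.13) and at or above the median level (0.38), and, without rows 1 to 128, germline genes (0.47) and mast cell markers (0.48). Glycolysis after normexp (-0.0445), dendritic markers at or above the median level (0.23) and erythroid markers with no filter (-0.43) no longer passed it. Dnmt3a was at -2.45 with spike-in scaling. Mast cell markers had no value at or above the median level. The shift with spike-in scaling and the smaller counts from fewer genes or a higher threshold follow from their construction; otherwise the cause was not tested. Signal over background limits the dim genes, where the scanner error grows.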

Other observations

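The tests of the level-dependent trend, of the osteoclast share and of the macrophage share were chosen after the result was seen, as was the grouping of genes by the start of their symbols; the test without rows 1 to 128 and the collagen test were written down before their results.

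Groups of genes that share the start of their symbol (156 groups of at least 10 measured genes) showed further sets, which overlap the fixed lists in part. Below nearly all matched random lists lay the collagens (Col, 25 genes, median -0.70, led by Col5a3 at -1.36 and Col10a1 at -1.14, some of them on the stromal list), the matrix metalloproteinases (Mmp, 10 genes, -0.41, with Mmp13 at -0.93; Mmp9 and Mmp14 are also on the effector list and Mmp8 on the neutrophil list) and the semaphorins (Sema, 13 genes, -0.32, with 7 below and 6 above 0, from Sema3c at -1.21 to Sema6d, 2.01-fold higher). The Atp group (60 genes, -0.19, 45 of them below 0), which shares members with the oxidative phosphorylation and proton pump lists, lay below all 10000 random lists. Lower values of mitochondrial genes extended past the respiratory chain to the mitochondrial ribosome (Mrpl, 48 genes, -0.11, and Mrps, 29 genes, -0.13) and to the import machinery of the inner membrane (Timm, 14 genes, -0.22, with Timm8a1 at -0.48). Small shifts of this kind were not confined to mitochondrial genes. The Eif group (52 genes, -0.08, percentile 0.68) and the Fkbp group (13 genes, -0.20, percentile 0.61) were also below the range of random lists. The spots of Col5a3 and Sema3c lie in rows 1 to 128, and the genes named here were chosen after their values were seen. The mean levels of Col5a3, Col10a1 (SE 0.36) and Sema3c lie below the median of the measured genes.

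Above nearly all matched random lists lay the kallikreins (Klk, 13 genes, 0.65), many of which are near-identical copies that make their probes uncertain. The same held, with medians that the shift of 0.53 with spike-in scaling turns negative, for interferon-inducible Ifi genes (15 genes, 0.43, some also on the interferon list), Ly antigens (15 genes, 0.43, with Ly6a at 0.98 and Ly6c1 at 0.96), serpins of clade B (Serpinb, 11 genes, 0.45, with Serpinb8 at 0.90 and Serpinb10 at 1.12) and C-type lectins (Clec, 18 genes, 0.30). Cd38, an ectoenzyme that consumes NAD, was 4.08-fold higher on the knockout array (log2 difference 2.03, SE 0.22, 1 probe). Its spot lies at row 5, within rows 1 to 128, where those of Ly6a and Serpinb8 lie too. The mean levels of Cd38 and Serpinb10 lie below the median of the measured genes. These genes were chosen after their values were seen.

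Interferon genes (median 0.79) and macrophage markers (0.48) were higher while osteoclast effector genes (-0.50) and oxidative phosphorylation genes (-0.22) were lower. A trend with signal level or the spots of rows 1 to 128 do not account for it as a whole, since the interferon median was 0.77 after loess and 0.70 without those rows, above all 10000 random lists in both. A lower share of osteoclasts alone would raise the markers of every other cell type alike. Macrophage and stromal medians lay 1.01 apart (95% bootstrap interval over genes 0.79 to 1.42), which argues against this strict form only. The interval resamples genes of 1 array per genotype and does not cover the spread between cultures. Some genes of the stromal list are also expressed by osteoclasts or macrophages, and a lower osteoclast share with other changes stays open. A larger share of macrophages that brings the interferon genes with it cannot be told apart from an interferon response within the cells: the interferon median exceeded the macrophage median by 0.30 (interval 0.03 to 0.48), but its lower quartile (0.68) lay below the upper quartile of the macrophage markers (0.75). The genotype and a difference between these particular cultures stay open and untested with 1 array each, and that the knockout culture may have been less advanced towards osteoclasts is a hypothesis only.

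Stromal and osteoblast markers were lower (median -0.53), and a candidate explanation is fewer stromal cells in the knockout culture. It needs further stromal transcripts to be lower too, and the 20 collagen genes outside the list had a median of -0.61, below all 10000 random lists (-0.15 to 0.17). On the wild type and knockout arrays the log2 levels relative to the 75th percentile were 7.13 and 6.64 for Sparc, 6.07 and 5.37 for Col1a2 and 5.08 and 4.36 for Col1a1 (genes chosen after their values were seen), and Spp1 and Fn1 of the list are also expressed by osteoclasts or macrophages, while Dcn is also on the imprinted list. The protocol seeded nonadherent marrow cells, a step that would remove part of the stromal cells from either culture. Lower expression of these genes in the same cells, by genotype or by culture, would give the same medians and was not tested.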
